A study of Rattus norvegicus with 4 samples.

How the data were processed

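The series measured trimethylation of histone H3 at lysine 27 (H3K27me3), the mark that the Polycomb complex PRC2 places on silenced genes, in the sciatic nerve of male Sprague Dawley rats aged 42 postnatal days. The tissue came from the sham-operated side, which had a skin incision alone, collected 1 day after the nerve of the other side was cut. Per the labels, chromatin was digested with micrococcal nuclease and immunoprecipitated, and libraries were also made from the matching input chromatin. The 4 libraries fall into 2 groups, with 2 H3K27me3 libraries and 2 input libraries. Values of the transected side were not used here.

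The submitters' processing notes name CASAVA 1.8.2, the aligner Bowtie and the peak tool HOMER. Per the file headers, the peaks of the H3K27me3 sham libraries form a combined list, annotated with HOMER against the rat assembly rn5. The Bowtie version, the peak calling settings, the use of the input and the way the replicates were combined are not given in the sources used here. The peak score was deposited by the authors for each peak without a stated scale. Widths, coordinates and distances from a peak's centre to the nearest transcription start site (TSS) were also deposited by the authors, in bp. The width equalled the end minus the start in 100% of peaks. The list has a single value per peak and no value per library, so no spread between replicates can be given, genes are the units of every test, and p-values say only whether genes of a list stand apart from other genes of this pooled peak list. Scores were used only to describe, rank and filter peaks within it.

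The scores lie on a grid. For the 97601 peaks with a score under 10, 100% of the scores were whole multiples of 0.206271 within a rounding tolerance of 0.005, against a mean of 5.25% of the different scores for 20 other step sizes. The smallest score of 1.86 is 9 steps. The 95% counting intervals printed with scores treat each step as 1 sequenced tag, an assumption, and cover counting error only. The depth of each library is unknown.

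Genes were matched to a table of rat genes of the newer assembly GRCr8, used for names, chromosomes and neighbourhood only. Of the 10646 genes that the peak list names, 10566 matched by gene identifier and 10 more by symbol, together 99.3%. A peak names only the gene of the TSS nearest to its centre. A gene was counted as having a promoter peak where a peak assigned to it reached within 1000 bp of the TSS, that is, where the distance was no more than the sum of 1000 bp and the width divided by 2. The background held 23156 genes, the 23154 protein-coding genes of the table and 2 non-coding list members. A gene that no peak names counts as without a promoter peak, and it cannot be told from a gene absent from the authors' annotation.

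The gene lists, tests, alternatives and named genes were chosen before the data were examined, except where stated. The 20 lists were nerve injury and repair Schwann cell genes, neural crest and Schwann cell precursor genes, myelin and mature Schwann cell genes, sterol biosynthesis genes, Hox genes, neural fate transcription factors, mesoderm and endoderm transcription factors, developmental signalling ligands, neuronal function genes, housekeeping genes, fibroblast and perineurial markers, endothelial and mural markers, leukocyte and mast cell markers, adipocyte and skeletal muscle markers, liver genes, germ cell genes, cell cycle inhibitor genes, Polycomb and H3K27 demethylase genes, imprinted genes and chemosensory receptor genes. The rule for named genes took the 4 members of each list with the highest promoter peak score, up to 2 members without a promoter peak in list order, 14 genes named in any case (among them Shh, Gdnf, Olig1, Sox2, Jun, Ngfr, Bdnf, Fgf5, Runx2, Cdkn2a, Mbp, Egr2 and Sox10), and the 10 genes with the widest and the 10 with the highest-scoring promoter peak genome-wide. The genome-wide ranks cover background genes alone. Chemosensory receptors were described by counts alone. Genes named outside this rule are said to be so, and some genes that it takes are not reported here.

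List membership was tested against having a promoter peak with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. Odds ratios have 0.5 added to each cell and exact conditional 95% intervals, and shares have 95% Wilson intervals. For lists with at least 5 genes with a promoter peak, the median width of each gene's widest promoter peak and the median of its highest score were compared with random sets of other genes by a two-sided permutation test with 100000 resamples, whose smallest possible p is 2e-05, adjusted over those lists. Genes on the X chromosome were compared with autosomal genes by Fisher's exact test. Alternatives changed the promoter reach (0 or 5000 bp, or only peaks whose centre the authors' annotation calls promoter-TSS), the score minimum (the median of 4.54 or the top 25% of peaks, 9.9), the width minimum (2000 bp), the merging of peaks within 5000 bp, the background, and the unit of counting (loci of 200 kb). For widths and scores, the summary per gene was also changed, and scores were matched on width by broad classes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

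The tests were tested on simulated data, in which peaks and list members were drawn independently over genes. The rates of false calls for lists of neighbouring or better annotated genes were therefore not measured. Over 23154 genes, 1.14% of 350 simulated lists with an odds ratio of 1 were called higher and 1.14% lower. Of 300 lists simulated with an odds ratio of 4, 75% were called higher, and of 300 with an odds ratio of 10, 100% were. For width over 3978 genes, 0% of 103 lists without a shift were called wider or narrower, and 21.7% of 60 lists with widths shifted by 1 on the log2 scale were called wider, so the width test misses most shifts of that size.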

Results

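H3K27me3 was profiled in the uninjured, sham-operated sciatic nerve of adult male rats, a tissue of Schwann cells, fibroblasts, perineurial, endothelial and immune cells around axons whose cell bodies lie elsewhere. The nerve had 2 H3K27me3 libraries and 2 input libraries, and the authors combined the H3K27me3 peaks into a single list on rn5. The list held 129550 peaks on 21 chromosomes that covered 67.7 Mb. There are no values per replicate, so counts and scores stand without a replicate error, and the score is the authors' own value per peak.

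The first question was where in the genome of the resting nerve the mark lay. Most peaks lay away from the genes of the authors' annotation. By the position of their centre, 74.7% (95% Wilson interval 74.5 to 74.9%) were intergenic, 21.8% intronic and 1.63% (1.56 to 1.70%, 2106 peaks) in the authors' promoter-TSS class. The share of the genome in each class was not computed, so these shares show no enrichment, and their intervals treat peaks as independent. The median distance to the nearest TSS was 35622 bp. The peaks were mostly short, with a median width of 191 bp (quartiles 150 and 427 bp), and 58590 (45.2%) had the smallest width of 150 bp. A small set of broad peaks carried much of the signal. The list held 1313 peaks of at least 5000 bp, 336 of at least 10000 bp and 55 of at least 20000 bp, and the top 1% of peaks by score (1296 peaks) held 29.6% of the summed score. Width and score went together across peaks (Spearman rho 0.918, across peaks, which are not independent replicates). Broad peaks reached promoters more often than short ones, in part by definition, since the reach includes the width. Of the peaks of the smallest width 1.94% reached within 1000 bp of their nearest TSS, of those between 1 and 5 kb 18%, and of those over 10 kb 57.4%. Restricting the list to peaks with a score at or above the median gave a median width of 420 bp and a promoter-TSS share of 2.30%.

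The broadest promoter domains covered genes that specify body axis, organs and brain regions. The widest promoter peak lay over Hoxb8 (chromosome 10, 83909652 to 83957491, 47839 bp, score 3183, 95% counting interval 3133 to 3234), a gene of the Hoxb cluster that patterns the body axis. It was followed by Gata4 (chromosome 15, 50182530 to 50229622, 47092 bp, score 3590.4, the highest of all promoter peaks), a regulator of heart and gut development, and by Otx2 (45085 bp), a forebrain and midbrain gene. Sox2 (36268 bp), Sim1 (34161 bp), Nkx2-1 (34151 bp), Pax6 (32594 bp), Fev (32519 bp) and Onecut1 (30168 bp) were also among the 10 widest of the background genes. Among the background genes, the 10 highest scores belonged to Gata4, Hoxb8, Pax6 (2802), Nkx2-3 (2450.1), Sim1 (2388), Otx2 (2168), Vax2 (2139), Nr2e1 (2121), Pax2 (2084) and Nkx2-5 (2081). In all, 6226 peaks (4.81%) were promoter peaks, and 3979 of the 23156 background genes (17.2%) had at least 1.

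The lists fixed for the study's tissue and mark were then compared with the background. Of the 20 lists, 13 had promoter peaks more often than other genes, 3 less often, and 4 did not pass the threshold.

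**Figure D1:**
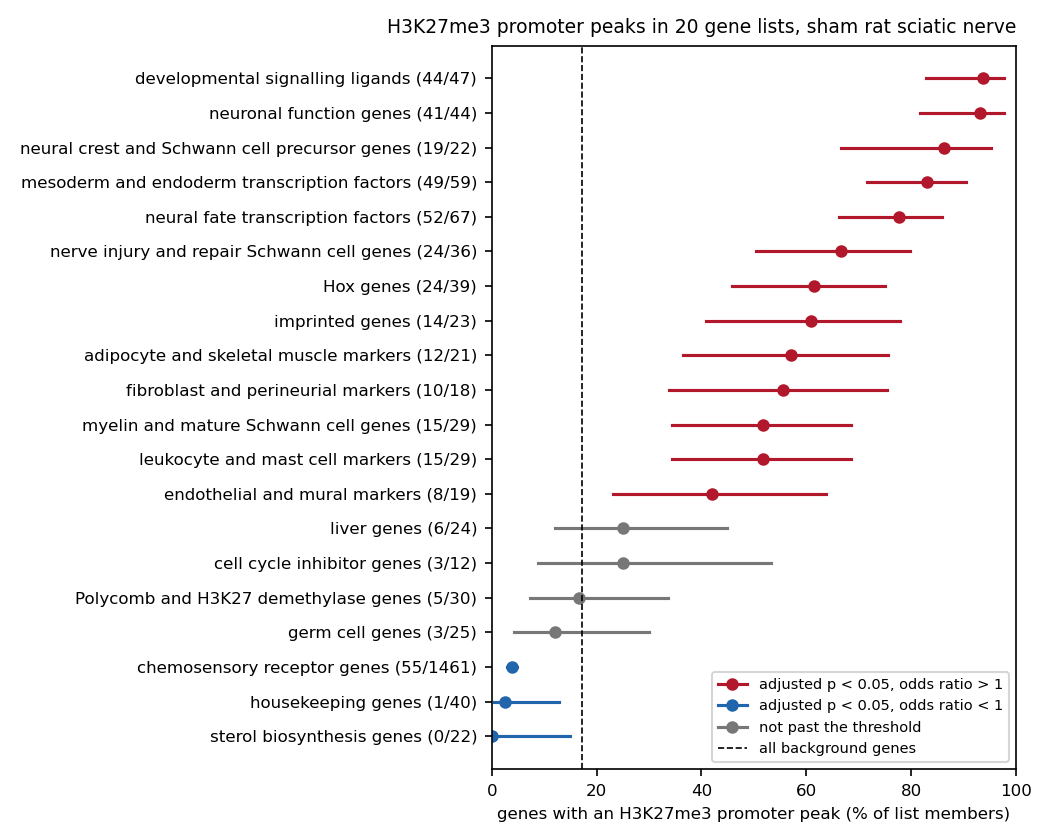
Share of the members of each of the 20 gene lists with an H3K27me3 promoter peak, in percent, with 95% Wilson intervals as bars and the counts beside each name. Developmental signalling ligands (44 of 47) and neuronal function genes (41 of 44) lie highest, sterol biosynthesis genes (0 of 22) and housekeeping genes (1 of 40) lowest, and the dashed line marks the 17.2% of all background genes.

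Many genes that Schwann cells use after nerve injury carried the mark in the resting nerve. Of 36 nerve injury and repair Schwann cell genes, 24 had a promoter peak and 22 had one in the top 25% of scores. Shh, a morphogen made by Schwann cells distal to a cut, lay under a peak of 10795 bp (chromosome 4, 712106 to 722901, centred in intron 1) with a score of 450.7 (counting interval 432 to 470.0). Gdnf, a survival factor for motor neurons, had a peak of 9500.0 bp (chromosome 2, 76897115 to 76906615, intron 1) with a score of 480.6 (461 to 501). Olig1, an oligodendrocyte lineage factor, had 8897 bp (chromosome 11, 35034187 to 35043084, centred in its 3' UTR) and 440.6. The neurotrophin Bdnf (8583 bp, 377.3), the growth factor Fgf5 (7579 bp, 362.2), the neurotrophin receptor Ngfr (6321 bp, 288.4) and Runx2 (3121 bp, 188.5) followed, the last a transcription factor best known from bone. The highest scores of the list belonged to Sox2 (chromosome 2, 140796892 to 140833160, score 1929.9), a factor of immature Schwann cells, and to the adjacent cell cycle inhibitors Cdkn2b (chromosome 5, 111811038 to 111826998, 15960 bp, 1019) and Cdkn2a (111799640 to 111809234, 9594 bp, 735.8).

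Other genes of the injury response had no promoter peak. Jun, the transcription factor at the centre of the repair programme, was the nearest gene of 8 peaks, of which the closest was centred 8834 bp from its TSS and the highest, 66514 bp away, scored 44.8. Clcf1 also had none, and neither did, outside the naming rule and picked after their values were seen, Atf3, Sox4, Megf10, Ucn2, Hbegf, Btc, Il6, Ccl2, Gfap and Sema4f. The list was enriched (odds ratio 9.50, 95% interval 4.66 to 21.3, adjusted p = 1.7e-10, Fisher's exact test), less so against the genes named in the peak list alone (3.74, 1.77 to 9.03, adjusted exact p = 6.4e-04). The median width of its promoter peaks was 4377 bp against 1341 bp in other genes with a promoter peak (adjusted p = 4.1e-04), and the median score 189 against 40.4 (adjusted p = 1.4e-04, both permutation tests). Counting only peaks centred in the promoter-TSS class gave an odds ratio of 2.82 with an adjusted exact p of 0.0580, loci of 200 kb gave 2.43, and the score did not stand apart from genes with peaks of like width (ratio 1.15, adjusted permutation p = 0.539).

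**Figure D2:**
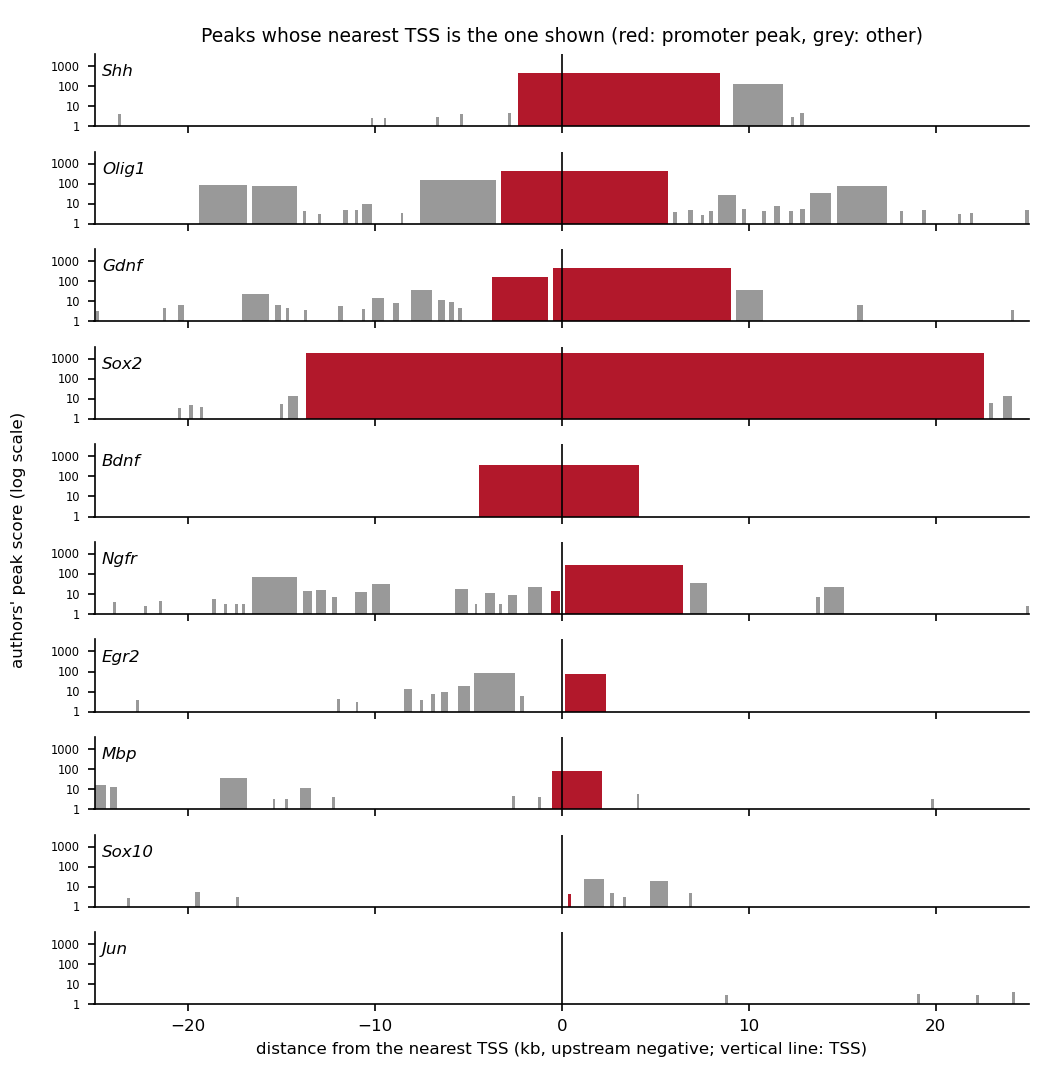
Peaks around 1 TSS each of 10 named genes, for peaks to which that TSS is nearest, drawn from 25 kb upstream to 25 kb downstream, with the height showing the authors' score on a log axis, promoter peaks in red and others in grey. Shh, Olig1, Gdnf, Sox2, Bdnf and Ngfr have broad promoter peaks with scores from 288.4 to 1929.9, Sox10 a peak of 150 bp, and Jun none.

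Most genes of the developmental stages before the Schwann cell carried the mark. Of 22 neural crest and Schwann cell precursor genes 19 had a promoter peak, led by Zic1 (score 2017, 30065 bp), Dlx5 (1853), Zic2 (1476) and Pax3 (1471, 17912 bp), factors of the neural plate border and neural crest. Foxd3 and Dlx6 had none, although the domain of Dlx5 lies beside Dlx6, and no peak names Foxd3. The odds ratio was 27 (9.02 to 162, adjusted p = 8.5e-12, Fisher's exact test). The median width was 11930.0 bp and the median score 674.5, against 1343 bp and 40.6 in other genes (adjusted p = 5.3e-05 for each, from the smallest p the 100000 permutations can give).

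Mature Schwann cell genes were divided. Of 29 myelin and mature Schwann cell genes, 15 had a promoter peak. Peaks name 19 of the 29, and the others cannot be told from genes absent from the authors' annotation. The highest scores belonged to Dhh (436.7, placed on X in rn5 and on chromosome 7 in the newer assembly), a Schwann cell signal to the nerve sheath, Pou3f1 (272.7), which acts before myelination, Nfasc (143.4) and Mpp6 (125.8). Peaks of Mbp, which encodes a major myelin protein, were assigned to 2 TSS. The upstream TSS had a peak of 2634 bp with a score of 77.4 (chromosome 18, 78384896 to 78387530). The downstream TSS had no promoter peak, and its closest peak was centred 17145 bp away. Mbp counts among the 15 by the upstream TSS alone. Which TSS serves the myelin protein was not examined, so the mark is not shown to lie at its promoter. Egr2, the master regulator of myelination, had 2215 bp and 72.6 (chromosome 20, 24553848 to 24556063, intron 1). At Sox10, the lineage factor, the promoter peak was of the smallest width, 150 bp, with a score of 4.13 (2.52 to 6.37). Pmp22 and Mag had none.

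The myelin list had an odds ratio of 5.17 (2.33 to 11.6, adjusted p = 4.1e-05, Fisher's exact test), and its median width of 2634 bp was not separated from that of other genes (1352 bp, adjusted p = 0.194, permutation test). When the peak had to contain the TSS the odds ratio was 2.70 (adjusted exact p = 0.180), with loci of 200 kb it was 1.44, and with peaks centred in the promoter-TSS class 1.96, none past the threshold. Sterol biosynthesis genes, which supply cholesterol for myelin, had no promoter peak in 22 genes (0%, Wilson upper bound 14.9%), Hmgcs1 included. Their odds ratio was 0.107 (0 to 0.879, adjusted p = 0.0291, Fisher's exact test), a call that stricter scores ended (0.129, adjusted p = 0.0793, at or above the median) and that a reach of 5000 bp ended too (0.318, adjusted p = 0.0702).

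Regulators of other lineages had many of the broadest and highest-scoring peaks. Of 67 neural fate transcription factors 52 had a promoter peak, led by Pax6, Sim1, Otx2 and Pax2, and of 59 mesoderm and endoderm transcription factors 49 did, led by Gata4, Nkx2-5, Foxa1 (1753) and Wt1 (1743). No peak names Neurog2 or Foxf1, and Neurod4 and Foxf2 also had no promoter peak. Peaks name 53 of the 67 and 53 of the 59. The unnamed genes are not shown to lack the mark, since a domain assigned to a neighbouring gene does not count for them. The odds ratios were 16.5 (9.37 to 32.4, adjusted p = 1.1e-26) and 23.0 (11.9 to 53.0, adjusted p = 1.4e-27, Fisher's exact test). Median widths were 13568 bp and 10698 bp, and median scores 985 and 648.7, all with an adjusted permutation p of 5.3e-05, again from the smallest p possible. Of the 39 Hox genes 24 had a promoter peak, led by Hoxb8, Hoxc11 (1894), Hoxb13 (1822) and Hoxc12 (1711), with an odds ratio of 7.66 (3.90 to 15.9, adjusted exact p = 1.8e-09) and a median width of 10382 bp. The other 15, among them Hoxa3 and Hoxa4, are named by no peak, so a domain that spans several Hox genes counts for 1 of them. Of the peaks over 10 kb only 4.17% were centred in the promoter-TSS class, and that class gave odds ratios of 1.38, 1.59 and 2.15 for the neural fate, mesoderm and endoderm, and Hox lists, none past the threshold.

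In the main setting, signalling ligands and neuronal genes had the highest shares of all lists. With peaks that contain the TSS, neural fate factors ranked higher (46 of 67, against 28 of 47 ligands and 24 of 44 neuronal genes). Of 47 developmental signalling ligands 44 had a promoter peak, with Wnt3a (763.4), Gdf6 (672.2), Wnt1 (663.6) and Wnt16 (581.1) at the top and Wnt2 and Wnt5b among those without (odds ratio 61.9, 22.9 to 359.9, adjusted exact p = 1.7e-29). Of 44 neuronal function genes 41 had one, led by the GABA transporter gene Slc32a1 (960.8), the GABA-synthesising enzymes Gad1 (753.9) and Gad2 (733.5), and the neurofilament gene Nefl (575.9). Slc6a4 and Scn2a had none (odds ratio 57.7, 21.2 to 336, adjusted p = 1.4e-27, Fisher's exact test). Against the genes named in the peak list alone the odds ratios were 47.9 for ligands and 19.1 for neuronal genes, and with loci of 200 kb 14.6 and 21.97. The ligands' peaks had a median width of 4977 bp and those of neuronal genes 3009 bp (adjusted p = 5.3e-05 and 0.0028, permutation tests), but with peaks within 5000 bp merged the width of neuronal genes was no longer past the threshold (ratio 1.62, adjusted permutation p = 0.0674). Matched on width, the scores of neither list stood apart (adjusted permutation p = 0.0790 and 0.747).

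**Figure D3:**
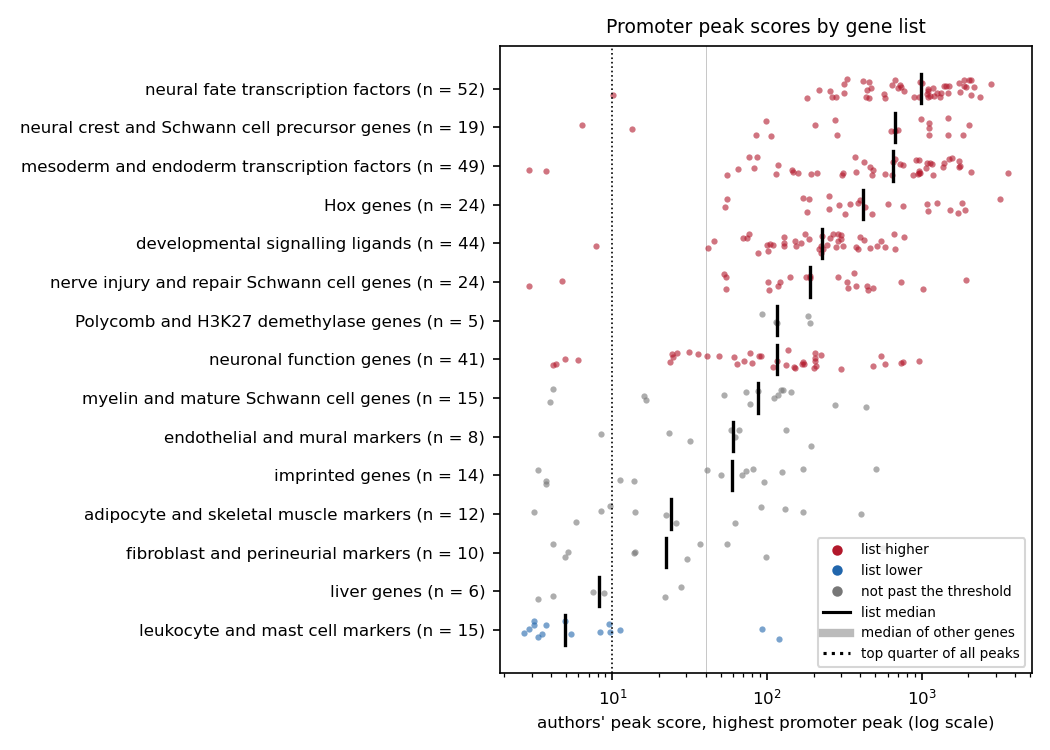
Authors' score of the highest promoter peak of each list gene (points, log axis) for 15 lists with at least 5 such genes, chemosensory receptors left out, with the list median as a black bar, the median of other genes near 40 as a grey line and the limit of the top 25% of all peaks (9.9) dotted. Neural fate transcription factors have the highest median (985) and leukocyte and mast cell markers the lowest (4.95).

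Markers of cell types other than Schwann cells, skeletal muscle among them, had promoter peaks more often than the background. For fibroblast and perineurial markers the count was 10 of 18 (odds ratio 5.97, adjusted exact p = 3.9e-04), with Pdgfra (561.3), Thy1 (98), Cldn1 (55.1) and Fn1 (36.7) highest and none at Col1a2 and Col3a1. For endothelial and mural markers it was 8 of 19 (odds ratio 3.57, adjusted p = 0.0133, Fisher's exact test), with Cnn1 (192.7), Cldn5 (132.4), Kdr (65.6) and Erg (61.7) and none at Pecam1 and Cdh5. Adipocyte and skeletal muscle markers had 12 of 21 (odds ratio 6.36, adjusted exact p = 6.8e-05), with Acta1 (403.1), Pvalb (171.6), Pparg (130.6) and Des (90.8) and none at Cidec and Myh4. Leukocyte and mast cell markers had 15 of 29 (odds ratio 5.17, adjusted exact p = 4.1e-05), of which only 3, at Kit (119.8), Cd8a (93.0) and Cx3cr1 (11.1), lay in the top 25% of scores. Cd3e followed with 9.69, and Ptprc and Csf1r had none. The leukocyte peaks were narrower than those of other genes, with a median of 234 bp (adjusted p = 0.0092), and lower in score, with a median of 4.95 (adjusted p = 0.0043, permutation tests), but not lower than in genes with peaks of like width (ratio 1, adjusted permutation p = 1.0).

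The 4 calls on these cell types did not hold under every setting. With the genes named in the list of peaks as the background, the endothelial odds ratio was 1.81 (adjusted exact p = 0.341), and the leukocyte odds ratio was 0.912 (adjusted exact p = 1.0) when peaks of the top 25% alone were counted and 0.802 when the peak had to contain the TSS. The fibroblast odds ratio was 2.31 (adjusted exact p = 0.381) when the peak had to contain the TSS, and that of adipocyte and muscle markers 3.50 (adjusted exact p = 0.0856) with peaks of at least 2000 bp. After peaks within 5000 bp were merged, the leukocyte and chemosensory peaks were no longer narrower (width ratios 1.72 and 1.29).

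Among the remaining lists, imprinted genes had 14 promoter peak genes of 23 (odds ratio 7.38, 3.03 to 19.7, adjusted exact p = 7.3e-06), with the growth factor gene Igf2 (508.5), Ascl2 (171.6), Dlk1 (124.4) and Phlda2 (95.1) at the top and none at Peg10 and Cdkn1c. Only 1 of 40 housekeeping genes had a promoter peak, Chmp2a with a score of 4.54, and Actb and Gapdh had none (odds ratio 0.183, 0.00305 to 0.729, adjusted exact p = 0.0133). Of 1461 chemosensory receptor genes 55 had one (3.76%, odds ratio 0.179, 0.132 to 0.233, adjusted p = 2.0e-58, Fisher's exact test), with a median width of 282 bp. Peaks name only 239 of these receptors, and the others cannot be told from genes absent from the authors' annotation. The size of this contrast therefore depends on the background. Lists without a call were liver genes, 6 of 24 (odds ratio 1.69, adjusted exact p = 0.335), led by Arg1 (27.6), Fgg (21.9), Fgb (8.87) and Alb (7.43) with none at Apoa1 and Apoa2, and germ cell genes, 3 of 25 (0.749, adjusted exact p = 0.831), Prm1 (21), Sycp2 (4.13) and Boll (3.51), with none at Ddx4 and Dazl. Cell cycle inhibitor genes had 3 of 12 (1.78, adjusted exact p = 0.494), which were Cdkn2b and Cdkn2a, also in the injury list, and Tp73 (3.92), with none at Cdkn1a and Cdkn1b. Polycomb and H3K27 demethylase genes had 5 of 30 (1.04, adjusted exact p = 1.0). These were Cbx8 (188.1), Cbx7 (183.4), Pcgf5 (115.9), Bmi1 (113.9) and, outside the naming rule, Cbx2 (92.0), all subunits of the PRC1 complex, and Ezh1 and Ezh2 of PRC2 had none. The housekeeping call ended when the peak had to contain the TSS (0.188, adjusted exact p = 0.251) and with a reach of 5000 bp (0.682), and the imprinted call ended when the peak had to contain the TSS (3.53, adjusted exact p = 0.0989).

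The last comparison set the X chromosome, present as 1 copy in males, against the autosomes. Promoter peaks were found at 81 of 936 X-linked genes (8.65%, Wilson interval 7.02 to 10.6%) and at 3898 of 22140 autosomal genes (17.6%), with chromosomes taken from the newer assembly. The odds ratio was 0.446 (0.348 to 0.559, p = 2.0e-14, Fisher's exact test). In the assembly of the peak list X held 1285 peaks, or 8.32 per Mb, against 30.1 (chromosome 2) to 81.5 (chromosome 10) on the autosomes. Against the genes named in the peak list alone, the odds ratio was 0.769 (exact p = 0.0542). That background by construction leaves out the X-linked genes that no peak names.

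**Figure D4:**
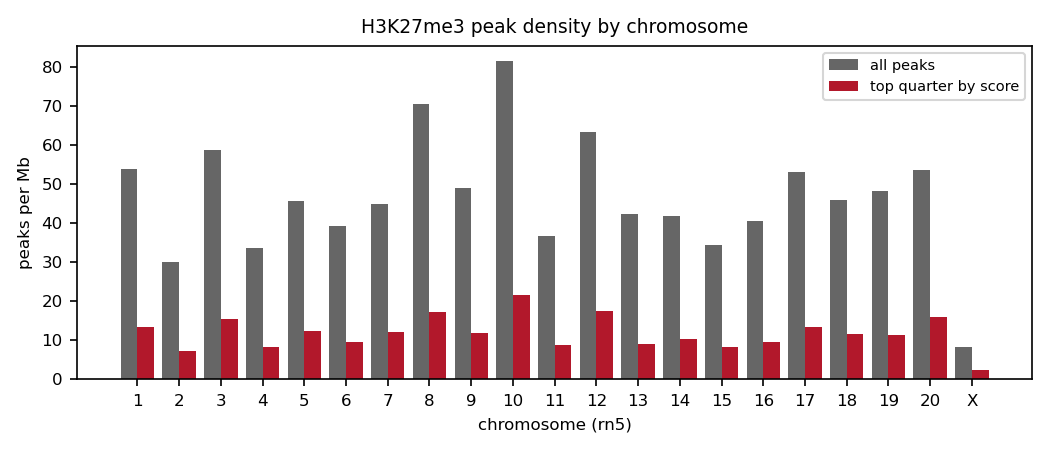
Peaks per Mb on each chromosome of rn5, with the length taken as the end of the last peak, for all peaks (grey bars) and for those in the top 25% of scores (red bars). X has 8.32 peaks per Mb and 2.35 of the top 25%, below every autosome in both.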

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

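In this part, the tests on copies of sequence and on developmental domains were chosen only after the result was seen, and the test on satellite repeats before.

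Some of the strongest signal lay in parts of the peak list that the comparisons did not use. The peak over a 5S rRNA repeat on chromosome 19 (67047804 to 67049004) had a score of 3560.2 in 1200 bp, and the highest score of the whole list, 4010.3, belonged to an intergenic peak of 2053 bp on chromosome 4 (6890394 to 6892447), at a deposited distance of -25895 bp from the nearest TSS. Annotated repeats lay at the centre of 31.1% of all peaks (40270 peaks) and of 26.3% of those in the top 25% of scores. Of the 263 non-coding genes that the peak list names, 90 (34.2%) had a peak reaching their TSS. The 4 highest scores among them, named after their values were seen, belonged to Mir9-1 (2115, 27594 bp), LOC102553190 (2098, 30973 bp), Mir3597-3 (1432) and Mir183 (1120.1). The input was not used here, so these signals have no background level beside them.

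Peaks with a very high score per kb gathered in a few places. The densest 0.1% of peaks (130 peaks, at least 82.3 per kb against a median of 22.9) included 86 within 1 Mb of another and 34 on chromosome 20. Sequence held in several copies is a possible explanation that stays open. An MHC (RT1) gene was nearest to, or an rRNA repeat lay at, 31 of the 130. However, 28 of these lay within 1 Mb of one of the first 30, from which the classes were picked. Away from those places, 4 of 55 windows of 1 Mb with a dense peak held such a peak, against 16 of 2357 other windows (odds ratio 12.4, 2.69 to 37.2, Fisher's exact test), and 4 windows are too few to decide. Strong developmental domains are a possible explanation for another part. Of the 29 dense promoter peaks, 8 belonged to transcription factor or Hox list genes, against 160 of 6197 others (odds ratio 14.9, 5.41 to 34.4, and 7.41, 2.44 to 18.7, by windows of 1 Mb), while the other 101 dense peaks were no promoter peaks. The promoter peaks of these lists were already known to score high (median 58.1 per kb), and width was not matched. This test therefore adds little independent support. Satellite repeats lay at the centre of 0 of the 130, too few overall (65 of 129420 others) to decide. Several of the first 30 were centred in LTR repeats, among them RMER12B repeats on chromosome 4, a class that was not tested. No other explanation was tested.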

How the results depend on the processing

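Of the alternatives here, the background of genes with a curated transcript and the count of every peak near a rebuilt TSS were chosen only after seeing the data. No paired analysis was possible because the libraries share replicate numbers in the labels but the peak list holds pooled values without any per library, and for the same reason no replicate could be left out. Of 222 odds ratios under alternatives, 173 kept their direction and side of the threshold, 32 were no longer past it, 1 came to pass it and 16 reversed, of which 2 came to pass it on the other side. No setting changed the depth, and the smallest score is 9 steps. Except where stated, the cause was not tested.

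When the peak had to contain the TSS, 8 lists were higher and 1 lower, and the odds ratios no longer past the threshold were 2.70 for myelin, 0.339 for sterol, 0.188 for housekeeping, 2.31 for fibroblast, 3.24 for endothelial and 3.53 for imprinted genes, with leukocyte (0.802) and Polycomb genes (0.250) reversed. With peaks centred in the promoter-TSS class, 7 lists were higher and 1 lower, with injury 2.82, myelin 1.96, sterol 0.246, Hox 2.15, neural fate 1.38, mesoderm and endoderm 1.59, housekeeping 0.420 and endothelial 2.35 no longer past the threshold, and germ cell (1.18) and Polycomb genes (0.181) reversed. This setting by construction leaves out broad peaks centred beside a promoter. With a reach of 5000 bp, 1 list was lower, sterol (0.318) and housekeeping (0.682) lost the call and germ cell genes reversed (2.42).

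With scores at or above the median, sterol (0.129) and leukocyte genes (2.30) lost the call, the promoter-TSS share was 2.30%, the intergenic share 73.5% and the median width 420.0 bp. With the top 25% of scores, sterol was 0.153, and leukocyte (0.912) and liver genes (0.767) reversed. With a width of at least 2000 bp, 1 list was lower, and sterol (0.302), housekeeping (0.168), fibroblast (2.06), endothelial (2.89), leukocyte (1.24) and adipocyte and muscle genes (3.50) lost the call, with liver reversed (0.277). With fewer peaks the smaller lists have fewer genes to count.

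Against genes named in the peak list, endothelial (1.81) and X (0.769, exact p = 0.0542) lost the call and liver (0.769) and Polycomb genes (0.650) reversed. By construction this background leaves out every gene that is nearest to no peak, so it cannot show a lack of peaks at such genes. Against genes with a curated transcript, endothelial was 2.71 (adjusted exact p = 0.0556) and Polycomb reversed (0.790). Counting every peak near a rebuilt TSS added 22 genes and changed no call. A TSS was rebuilt from peak distances only for promoters that several peaks name, in 9208 genes. Genes that no peak names could therefore not be added, and this setting cannot test that limit. With loci of 200 kb, 8 lists were higher and 6 lower. Windows of background genes hold several genes each, which raises their share to about 42.7% by construction. Myelin (1.44), fibroblast (1.88), leukocyte (1.07) and adipocyte and muscle genes (2.06) lost the call, germ cell genes gained one (0.229), liver (0.345) and Polycomb genes (0.268) reversed and gained one, and endothelial (0.993) and cell cycle inhibitor genes (0.353) reversed. The 8 lists still higher had odds ratios of 2.43 to 21.97, against 7.38 to 61.9 in the main setting.

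With peaks merged, no list was narrower (0), the Polycomb odds ratio was 0.993, and the width ratios of endothelial (0.719), leukocyte (1.72), adipocyte and muscle (1.06), liver (1.35) and chemosensory genes (1.29) reversed, while that of neuronal genes (1.62) lost its call. Scores matched on width left 4 lists higher and 0 lower, with myelin (0.931) and Polycomb genes (0.858) reversed. The matching used classes of width, the widest without an upper limit. The 4 lists had median widths of 10382 to 13568 bp, and their matched genes median scores of 214 to 252. All peaks over 10 kb had a median score of 852.85, so the higher scores of these lists are not shown to be independent of width. Of the 82 named genes with a promoter peak, the score was the same for 53 when the peak had to contain the TSS (27 had no peak left), 72 with a reach of 5000 bp, 10 in the promoter-TSS class (62 had none left) and 1 after merging, which adds up scores.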

Other observations

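In this part, the tests on gene families, on the X chromosome, on peaks near the calling limit and on other cell types were chosen only after the result was seen, and the test on peaks beside the TSS before.

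Gene families, members of the fixed lists included, were grouped by the root of their symbol, and 146 families of at least 15 genes were tested with Fisher's exact test and Benjamini-Hochberg adjustment. Promoter peaks were more frequent in 17 families, Wnt and Sox, which lie mostly within the lists, included. The genes named here with a score are among the highest-scoring of each family and were picked after their values were seen. Among those that the lists hold in small part or not at all, inward rectifier potassium channels had them at 11 of 15 genes (Kcnj, odds ratio 12.3, adjusted exact p = 3.7e-05), led by Kcnj5 (score 314.2) and Kcnj9 (223.4), and synaptotagmins, the calcium sensors of vesicle release, at 12 of 17 (Syt, 11, adjusted exact p = 2.8e-05), led by Syt6 (368.6). Cyclic nucleotide phosphodiesterases had them at 16 of 26 (Pde, 7.60, Pde10a 306.7) and carbonic anhydrases at 10 of 17 (Car, 6.76, Car4 793.5). The root Rgs, mostly regulators of G-protein signalling, had them at 13 of 25 (5.22, Rgs6 111.6). Collagens had them at 21 of 44 (Col, 4.43, Col2a1 325.9), keratins at 24 of 55 (Krt, 3.76, Krt18 229) and solute carriers at 125 of 382 (Slc, 2.39, Slc10a4 964.7). Keratin genes lie in clusters and are not independent.

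Promoter peaks were less frequent in 13 families, with the chemosensory receptor families Olr and Vom, already in the lists, included. Many members of some of these families have no curated transcript, and a gene absent from the authors' annotation can be named by no peak, so the counts that follow are those of genes with a curated transcript. The root Rpl, of cytosolic ribosomal proteins, had them at 0 of 59 such genes (odds ratio 0.0307, adjusted exact p = 3.0e-05, against 0 of 189 in the full background), and Rps, which also holds some kinases, at 1 of 48 (0.115, against 1 of 116). Mitochondrial ribosomal protein genes had them at 0 of 47 (Mrpl, 0.0385, adjusted exact p = 2.5e-04), translation initiation factors at 1 of 53 (Eif, 0.104), RNA polymerase subunits at 0 of 32 (Polr, 0.0563) and zinc finger protein genes at 20 of 254 (Zfp, 0.317, adjusted exact p = 3.6e-07). Against genes with a curated transcript, 16 of the 17 and 11 of the 13 calls held, with Mmp, Znf and Smim the exceptions.

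The X chromosome held fewer peaks than halved autosomal scores would give, the case if scores scale with the number of copies. With every autosomal score halved and the same smallest score, the autosomes still had 28.7 peaks per Mb against 8.32 on X, a ratio of 3.45 (3.26 to 3.65), and in the top 25% of scores the ratio was 2.72 (2.45 to 3.03). Lower gene density alone does not account for it either, since X had 1.37 peaks per protein-coding gene against 4.09 (chromosome 19) to 7.63 (chromosome 13) on the autosomes. In the assembly of the peak list some genes lie elsewhere than in the newer one: 157 of the 1285 peaks of X lie at 114764573 to 116096346, near 30 genes now placed on chromosome 7, Dhh and Wnt1 among them, and 343 autosomal peaks lie near genes now placed on X, but counting each peak on the newer chromosome of its nearest gene gave X 1.56 peaks per gene against at least 4.03. Copy number, gene density and placement were each tested alone, so their joint effect stays open. The part of X to which reads can be assigned uniquely was not analysed here and stays open, and no other explanation was tested.

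Promoter peaks at mature Schwann cell genes in a tissue that contains mature Schwann cells were weighed against 3 explanations. Peaks near the calling limit cannot be the whole account, since 13 of the 15 genes (86.7%, exact interval 59.5 to 98.3%) had a peak in the top 25% of scores, as did 73.5% of other genes with a promoter peak, although that of Sox10 (4.13) lay near the smallest score of 1.86. Signal from other cell types in the nerve may contribute: the median score was 86.8 against 115.7 at neuronal function genes, a difference of -0.41 on the log2 scale with a permutation p of 0.600, which leaves this open because the shares of cell types are not known. Peaks beside rather than over the TSS may also contribute, with only 4 of the 15 containing the TSS (26.7%, exact interval 7.79 to 55.1%), but other genes with a promoter peak had 35.8%, and the interval reaches past 50%. No other biological explanation was tested.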
